A study of Homo sapiens with 9 samples.

How the data were processed

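The series holds 9 samples of HK-2 cells, namely 3 DDX18_WT and 3 DDX18A immunoprecipitations, 1 IgG control and 2 inputs. Peak lists of 7 libraries were used, and the inputs were not analysed here. Per the labels, an anti-DDX18 antibody was used on cell lysates, RNA was isolated with TRIzol and libraries were made with an NEBNext RNA kit. Per the submitters' processing notes, FastQC, Trimmomatic, STAR, featureCounts and DESeq2 were used with the human build GRCh38 (hg38), without stated versions. The peak caller, its threshold and the control it used are not given in the sources used here, so whether the folds are relative to input, IgG or local background is unknown.

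The authors deposited a list of peaks for each library, called per library and not on pooled samples. Per the file headers each line gives a peak's position, its fold enrichment (a ratio), its −log10 p and −log10 q values and a score, with the gene it overlaps and the part of the gene. The deposited score is 10 times the −log10 p value without its decimals. The smallest −log10 p in a list was 1.30 to 1.33, which corresponds to a p near 0.05. The values of a peak describe it within its own list only and were used for ranking and filtering there. A strong or deep library can give more and stronger peaks, and with no read counts in the lists depth per library is unknown. A shift in fragment length can also change the width and number of peaks. In 1 deposited list the names of the −log10 p and −log10 q columns were damaged, and these columns were read by position, since their values follow the order and ranges of the other lists.

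Lines with the same interval were counted as 1 peak. Starts were read as 0-based and are printed 1-based. Chromosomes 1 to 22, X, Y and the mitochondrial genome were kept, which leaves out 1 to 16 peaks per list. A peak's class was read at its centre from the authors' annotation as 5' UTR, exon, 3' UTR, intron or no gene. A gene was counted for a library when the authors' columns name it as overlapped by a peak. Of 13095 gene identifiers, 8887 (67.9%) came with a symbol, and 99.3% of the 8882 different symbols were found in the RefSeq gene table of the same build. Gene starts differed between the lists and RefSeq by a median of 0 bp, and 83.1% lay within 1000 bp. The lists give no strand, so overlapping genes cannot be told apart.

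Group means were compared by two-sided exact permutation of the 6 libraries (10 splits). Regions are merged peaks that overlap by 1 bp or more. Regions and genes were called exclusive when found in 3 of 3 libraries of a group and 0 of 3 of the other. Overlap with IgG was set against 100 random placements within chromosomes. The 22 gene lists, 13 of named members and 9 defined by symbol patterns, were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment at 0.05, first per group against all named genes with a peak in any of the 7 lists, then between genes of either group alone. Lists of snoRNA and small nuclear RNA genes had no measured member in the authors' gene columns and were read from RefSeq spans, adjusted within that reading. Wilson intervals have a level of 95% and cover counting error only. Genes named in the text follow a rule. CD44 and DDX18 were always named. Then came the 10 genes with a symbol seen in 3 of 3 libraries of a group and 0 of the other, and the 10 seen in all 6, with the highest median percentile of their best fold within a list, the same 5 without an IgG peak (DDX18A had 1 such gene), up to 4 members of each list that differ most in number of libraries, and 3 regions per direction. Members named beyond these, because they had peaks in all 6 libraries or belong to a count of 6, were chosen after their values were seen. Some members of the lists are not reported here by name.

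Alternatives fixed before the data were examined were a q of 1e-05 or less, equal numbers of peaks (3416 per list), removal of IgG-overlapping peaks, reciprocal overlap of 50%, all contigs, intergenic peaks given to the closest gene, RefSeq gene spans, leaving out each library, a replicate block, gene length as a covariate, a wider background of 59761 genes, and other minimum numbers of libraries. A q below 0.05 and leaving out DDX18A 1 and 2 together were added after seeing the data. Interval functions differed from brute-force counting in 0 of 80 checks on simulated data. On 20 simulated sets of 8882 genes with 100 planted exclusive genes per direction, 100% of these were recovered. They were planted by the rule that counts them, so this checks the counting and not how many bound genes real lists miss. In the simulated comparison of the groups, a list of 30 with 8 planted members was called in 17 of 20 sets and 0 of 380 null lists were called. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. No genome sequence was used here, so repeats and motifs were not examined.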

Results

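RNA bound to DDX18, a DEAD box RNA helicase of the nucleolus, was profiled by RNA immunoprecipitation sequencing in HK-2 cells, a human kidney proximal tubule epithelial line, after hypoxia and reoxygenation. In this assay an antibody pulls the protein out of a lysate and the RNA that comes with it is sequenced. The series sets wild-type DDX18 against the K116R form, each in cells deficient in their own DDX18. The labels name the groups DDX18_WT and DDX18A, and DDX18A is taken here as K116R because the design text names no other form. Peak lists of 3 DDX18_WT libraries, 3 DDX18A libraries and 1 IgG control library were analysed, while the 2 input libraries were not analysed here. No label says that the 3 libraries of a group came from separate cultures. Thus p-values of comparisons between libraries measure the spread between these libraries, which may be technical. The gene-list tests take genes as their units, so their p-values do not measure that spread. With 3 libraries against 3, the smallest two-sided exact p is 0.1, so no single comparison of library values could fall under 0.05. Read depth is unknown, since the lists hold no read counts. Every fold given for a peak is the authors' own value within its list. The IgG list held 50182 peaks, far more than any DDX18 list, and serves as background.

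The first comparison asks about CD44, the cell-surface receptor for hyaluronan, whose mRNA the series title names. CD44 (ENSG00000026508, RefSeq span on chromosome 11, 35139171 to 35232402, GRCh38) had a peak in 3 of 3 DDX18A libraries and in 0 of 3 DDX18_WT libraries (two-sided Fisher's exact test, p = 0.1). All 3 DDX18A libraries held a peak at the same place, running from the last exon into the 3' UTR. It spanned 35229250 to 35229385 in DDX18A 1, with a fold of 2.98, and 35229250 to 35229391 in DDX18A 2, with a fold of 3.59. In DDX18A 3 it spanned 35229157 to 35229394 with a fold of 6.29 and a −log10 q of 5.17, whereas q was 1 for this peak in DDX18A 1 and 2. DDX18A 2 held another CD44 peak at exon 3, from 35180274 to 35180407, with a fold of 2.78. The IgG list held 12 CD44 peaks, among them 35229113 to 35229497 with a fold of 11.3, which covers the last-exon peak of the DDX18A lists. Without peaks that overlap an IgG peak, 0 libraries of either group had a CD44 peak, and at a q of 1e-05 or less 1 library, DDX18A 3, kept it.

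**Figure D1:**
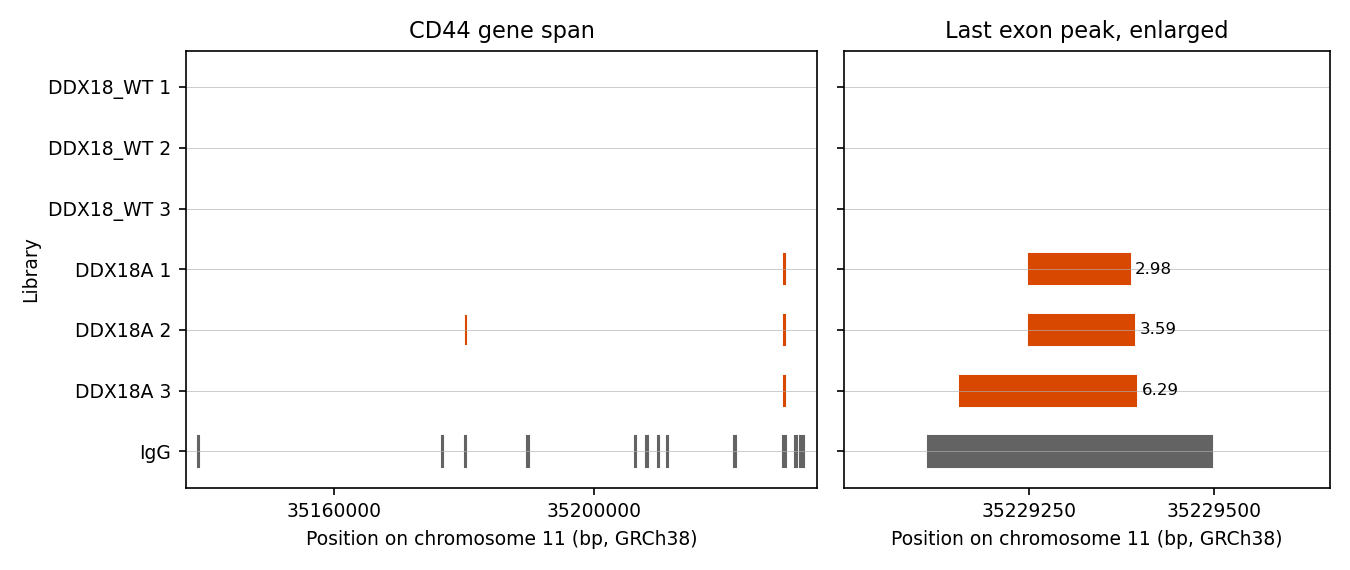
Peaks along CD44 in each of the 7 libraries, with the position on chromosome 11 (bp, GRCh38) on the horizontal axis and the library on the vertical axis. Each box is a called peak, orange for DDX18 libraries and grey for IgG. The right panel enlarges the last-exon peak, where numbers give the fold of 2.98, 3.59 and 6.29 in the 3 DDX18A libraries.

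DDX18 itself had no peak assigned to it by the authors in any DDX18 library. DDX18A 1 and 2 each had a peak starting at 117814778 on chromosome 2, with folds of 2.11 and 1.60 and a q of 1. That position lies inside the RefSeq span of DDX18 (117814691 to 117832377) but outside the gene model of the lists, which place the peak in no gene. An IgG peak at 117814670 to 117814888, with a fold of 11.7, overlapped both of these DDX18A peaks. The lists therefore do not check which form of DDX18 the cells held.

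The peaks of both groups lay mostly in introns, and exonic sequence took a larger share of them in DDX18A. Introns held 79.6% ± 0.313 (SD, n = 3) of the DDX18_WT peaks and 68.0% ± 1.55 (SD, n = 3) of the DDX18A peaks. Coding or noncoding exons and UTRs together held 9.24% ± 0.199 in DDX18_WT and 21.9% ± 1.28 in DDX18A, which is 2.37 times as much. Exons outside UTRs held 4.96% ± 0.211 and 13.0% ± 0.867, 3' UTRs 3.84% ± 0.0182 and 7.17% ± 1.41 and 5' UTRs 0.442% ± 0.0410 and 1.66% ± 0.650 (SD, n = 3 each). The groups did not overlap in any of these shares, and each gave the smallest exact permutation p of 0.1 (n = 3 per group), 0.1 after Benjamini-Hochberg adjustment over 5 classes. Peaks in no gene made up 11.1% ± 0.115 in DDX18_WT and 10.2% ± 0.286 in DDX18A, and with RefSeq gene spans that order turned, at 1.69% and 2.06%. In the IgG list 76.4% of peaks were exonic and 17.4% intronic. Counting error alone was small, for instance a 95% Wilson interval of 8.26% to 9.98% for the exonic share of DDX18_WT 2.

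**Figure D2:**
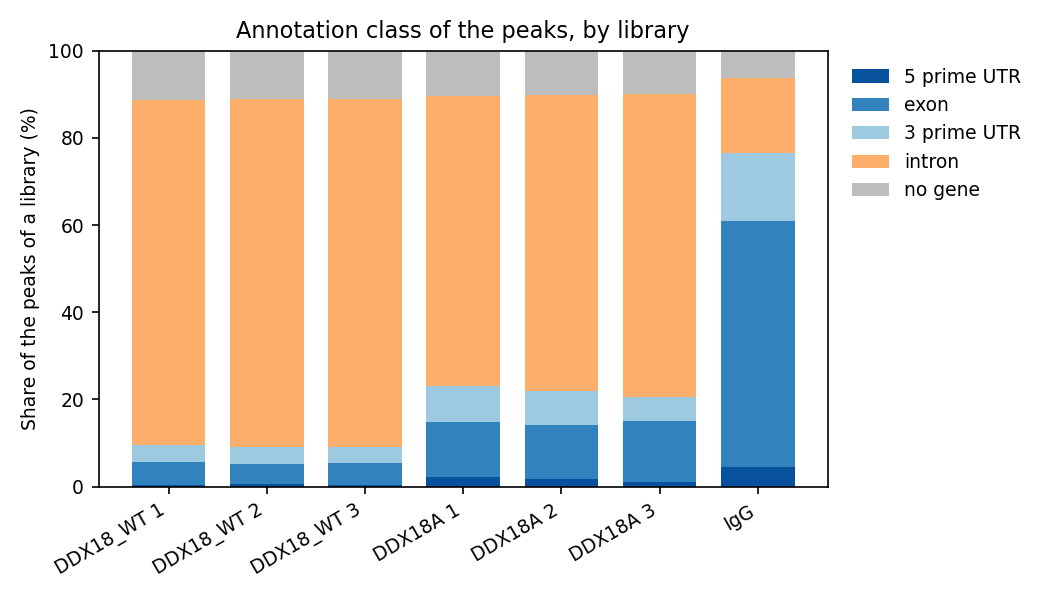
Share of each library's peaks (vertical axis, %) in each annotation class, for the 7 libraries on the horizontal axis. Blue parts are exonic and come to 9.24% on average in DDX18_WT, 21.9% in DDX18A and 76.4% in IgG.

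The number of peaks per library was 6379 ± 1956 (SD, n = 3) in DDX18_WT and 4235 ± 829 (SD, n = 3) in DDX18A. The groups overlapped, at 4295 to 8174 and 3416 to 5073 peaks. Their difference was not resolved (exact permutation test, p = 0.2, where 0.1 is the smallest possible). The peaks covered 2219 ± 663 kb and 1079.6 ± 489 kb (exact permutation p = 0.2, n = 3) and touched 2248 ± 494 and 1665 ± 396 genes (exact permutation p = 0.2, n = 3). Most peaks were weak, with a q of 1 for 98.0% ± 0.608 of the DDX18_WT peaks, 95.4% ± 0.714 of the DDX18A peaks and 23.5% of the IgG peaks. Among peaks with a q of 1e-05 or less the order of the groups turned, with a mean of 6.33 per DDX18_WT library and 21.7 per DDX18A library (exact permutation p = 0.1, n = 3). The narrowest peak was 133 and 134 bp wide in DDX18A 1 and 2, against 221 to 235 bp in the other 4 DDX18 libraries and 156 bp in IgG.

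Peaks that overlap an IgG peak by 1 bp or more made up 12.2% ± 0.431 (SD, n = 3) of the DDX18_WT peaks and 26.6% ± 2.29 (SD, n = 3) of the DDX18A peaks. The groups did not overlap (exact permutation p = 0.1, the smallest possible, n = 3). Random placement of the same peaks along their chromosomes gave 1.15% and 1.00%. Of exonic peaks, 63.4% ± 1.40 in DDX18_WT and 76.4% ± 1.21 in DDX18A overlapped an IgG peak. Among peaks free of IgG overlap, the exonic share was 3.85% ± 0.157 in DDX18_WT and 7.01% ± 0.270 in DDX18A (exact permutation p = 0.1, n = 3).

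Libraries of the same group shared more called sequence than libraries of different groups. The Jaccard index, the bp called in both libraries over the bp called in either, averaged 23.4% over the 3 DDX18_WT pairs, 21.6% over the 3 DDX18A pairs and 7.26% over the 9 pairs between groups. Within DDX18A the pair of libraries 1 and 2 reached 36.2%, while library 3 shared 14.0% and 14.6% with them. DDX18A 3 also shared more with the DDX18_WT libraries, 9.22% to 9.55%, than DDX18A 1 and 2 did, 5.53% to 6.89%. Lists that cover unequal amounts of sequence cannot reach a high index. DDX18A 1 and 2 covered 734 and 865 kb, and the other DDX18 libraries 1511 to 2825 kb. The mean within groups minus the mean between groups was 15.2 points, and the highest of the other 9 splits of the 6 libraries gave 3.36.

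**Figure D3:**
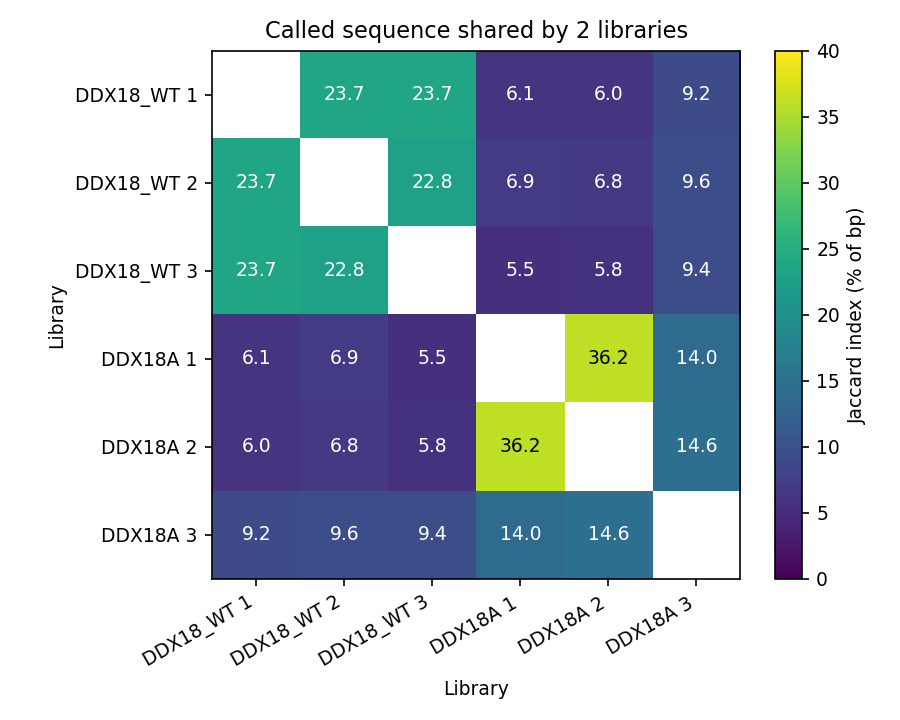
Jaccard index (% of bp) of each pair of the 6 DDX18 libraries, named on both axes, with the value in each cell. Pairs within DDX18_WT lie at 22.8% to 23.7%, DDX18A 1 and 2 at 36.2%, and pairs between groups at 5.53% to 9.55%.

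Merging the peaks of the 6 libraries gave 18283 regions, of which 940 were called in all 3 DDX18_WT libraries and no DDX18A library, 418 in the reverse pattern and 309 in all 6. Introns of ATAD2, a chromatin ATPase (chromosome 8, 123365925 to 123366466), NUP35, a nuclear pore protein (chromosome 2, 183146976 to 183147332), and TAOK1, a protein kinase (chromosome 17, 29418659 to 29419153), ranked highest among regions called in DDX18_WT alone, and none of the 3 overlapped an IgG peak. Exons of MT2A (chromosome 16, 56609263 to 56609486), YBX1 (chromosome 1, 42696629 to 42696860) and ASPH (chromosome 8, 61714269 to 61714498) ranked highest among those called in DDX18A alone, and all 3 overlapped an IgG peak. Exonic sequence held 7.45% of the regions of DDX18_WT alone and 25.8% of those of DDX18A alone, and 11.8% and 36.4% overlapped an IgG peak. The highest other split of the libraries gave 169 such regions in both directions together, against 1358. With equal numbers of peaks per library the counts were 467 and 349. Without DDX18_WT 1 or DDX18_WT 2 the count for DDX18_WT was 1457 or 1915, and without DDX18A 1 or DDX18A 3 the count for DDX18A was 689 or 1252. Leaving out a library loosens the rule, which by itself tends to raise such counts.

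At the level of genes, 197 had a peak in all 3 DDX18_WT libraries and no DDX18A library, and 60 the reverse. Of these, 168 (85.3%) and 56 (93.3%) had an IgG peak, near the 90.2% of all 4089 genes with a DDX18 peak. Of the 548 genes with a peak in exactly 3 of the 6 libraries, the 197 and 60 made up 46.9%. Chance would give 10% if all libraries called genes equally, which they did not, since the lists held 3416 to 8174 peaks. Of the named genes seen in DDX18_WT alone, nearly all were reached through an intron. NFXL1 (ENSG00000170448) had intron 18 peaks with folds of 1.65 to 4.26, and ALG13, a subunit of an enzyme of N-glycosylation, had intron 3 peaks with folds of 3.05 to 3.98. NDC80, a kinetochore protein, had intron 6 peaks (folds 2.57 to 3.84), and NOL11, a nucleolar protein of ribosome biogenesis, intron 7 peaks (folds 2.91 to 3.18). ZNF670, HERC4, PALS1 and HLTF likewise had intronic peaks, of which the strongest of PALS1 also lay within the RefSeq span of GPHN. SNRPD2, a core protein of spliceosomal particles, had exon 2 peaks instead, at folds of 2.53 to 3.68. Of the 156 genes of this pattern with a symbol, 145 had IgG peaks. CMC2, LRP12, ACYP1, ELOC and SLC30A7 are named for having none, and their peaks were intronic except for that of SLC30A7 in DDX18_WT 3, which lay in the 3' UTR. The counts depended on how many peaks each list held, since with equal numbers of peaks they came to 89 genes in each direction, of which 63 and 46 were among the 197 and 60. Without DDX18_WT 2 the count for DDX18_WT was 430, without DDX18A 3 it was 402, and the count for DDX18A was 188 without DDX18A 3 and 100 without DDX18A 1. Leaving out a library loosens the rule, so these counts could only rise. With each of the 6 libraries left out in turn they were 223 to 430 and 62 to 188.

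The named genes seen in DDX18A alone were reached mostly through exons and UTRs. Of the 49 genes of this pattern with a symbol, 48 had IgG peaks, as did 561 of the 568 with a symbol and a peak in all 6 libraries. MT2A, a metal-binding metallothionein, had last-exon peaks with folds of 15.1, 14.3 and 2.70 in DDX18A 1, 2 and 3, and its best IgG peak had a fold of 38.0. YBX1, a cold-shock RNA-binding protein, had folds of 13.0, 13.3 and 4.13. SPCS3, of the signal peptidase complex, and NUCKS1 had 3' UTR peaks at folds of 4.51 to 5.86 and 3.04 to 5.10. The ribosomal protein genes RPL3 and RPL30 had exonic peaks at folds of 2.68 to 6.05 and 2.78 to 5.11. PSMD12, a proteasome subunit (folds 5.29 to 5.73), and RBM39, a splicing factor (folds 3.82 to 5.28), had intronic peaks. CFL1, the actin-severing protein cofilin, shared its peaks with SNX32 in the gene model of the lists, and the strongest of them lay within the RefSeq span of CFL1 alone. RBPJ, the transcription factor of Notch signalling, is named for having no IgG peak and had folds of 1.66 to 3.87. Without peaks that overlap an IgG peak 24 genes were seen in DDX18A alone and 200 in DDX18_WT alone.

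Both groups had 648 genes with a peak in all 6 libraries. Those that ranked highest by fold within each list were mostly reached in intron 1. UBE2K, a ubiquitin-conjugating enzyme (chromosome 4, 39713223 to 39714399 in DDX18A 3), had folds of 6.12 to 9.89 over the 6 libraries, and ATXN2, an RNA-binding protein, had folds of 5.23 to 16.6, the highest from a peak that also overlaps the pseudogene IFITM3P5. The splicing-related genes SRPK2 (folds 4.50 to 6.12) and HNRNPC (4.29 to 7.61) were among them. So were SMURF2, a ubiquitin ligase of TGF-beta signalling (4.05 to 6.82), the polarity gene PARD3 (3.92 to 8.60), PIP5K1A (4.03 to 12.4), B4GALT5 (3.77 to 6.07), PPM1G (3.09 to 6.13) and C6orf62 (4.11 to 10.3). EEF1AKMT2, PWWP2A and EID3, which overlaps TXNRD1, had peaks in all 6 libraries and none in IgG, as did MEMO1, which shared its peaks with DPY30 in the gene model of the lists, while the strongest of them lay within the RefSeq span of MEMO1 alone.

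Gene lists fixed beforehand were tested among genes with a peak in at least 2 of 3 libraries of a group, against the 8882 named genes with a peak in any list, of which 19.9% had such peaks in DDX18_WT and 13.6% in DDX18A. Factors of mRNA decay and stability were over-represented in both groups, with 21 of 43 measured members in each (Fisher's exact test, adjusted p = 0.000252 in DDX18_WT and 1.22e-06 in DDX18A). CNOT1 of the deadenylase complex, the translational repressor PUM2, the exonuclease XRN2 and the helicase DDX6 had peaks in all 6 libraries. YTHDF3 had them in 3 DDX18_WT and 0 DDX18A libraries, IGF2BP1 in 1 and 3, and ELAVL1 and DCP2 in 0 and 2. Genes of TGF-beta signalling and epithelial-mesenchymal transition were over-represented in DDX18_WT, with 9 of 16 (Fisher's exact test, adjusted p = 0.0094). In DDX18A 6 of the 16 had peaks (adjusted p = 0.0862), and the difference between groups did not pass its own test (adjusted p = 1). SMAD2, SMAD3, SMAD7 and SKIL had peaks in all 6 libraries, whereas CDH2 and ZEB1 had them in 3 DDX18_WT and 0 DDX18A libraries, BMPR2 in 2 and 0, and SMAD4 in 3 and 1. Both calls held with gene length as a covariate (adjusted p = 0.00272, 1.14e-05 and 0.0489), and no member of these lists had such a peak at a q of 1e-05 or less or below 0.05, where the calls ended. The decay factors with peaks in DDX18A numbered 13 without DDX18A 2 or DDX18A 3, and those in DDX18_WT 14 without DDX18_WT 1 or DDX18_WT 3, where a group of 2 needs both, and the calls held (adjusted p = 0.000957, 0.00204, 0.0215 and 0.00855). Over all alternatives the adjusted p ran from 2.41e-07 to 1 for TGF-beta genes in DDX18_WT, and from 1.07e-19 and 6.74e-23 to 1 for decay factors in DDX18_WT and DDX18A. The TGF-beta list also passed in DDX18A with RefSeq gene spans (adjusted p = 0.00704) and against the wider background (4.88e-05).

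Histone genes had a peak in 0 of 56 measured members in both groups (Fisher's exact test, adjusted p = 0.000111 in DDX18_WT and 0.00448 in DDX18A). Ribosomal protein genes were under-represented in DDX18_WT, with 2 of 70 (adjusted p = 0.000577), and not in DDX18A, with 13 of 70 (adjusted p = 0.574). With gene length as a covariate the 3 calls ended (adjusted p = 0.429, 0.298 and 0.675). The odds ratio of ribosomal proteins in DDX18_WT moved from 0.117 to 0.628. For histone genes a covariate cannot change the count of 0 of 56, and given gene length that count no longer passed as too low. Gene length may therefore account for the absence of histone peaks, which a lost call alone does not settle. The 13 ribosomal protein genes of DDX18A were over-represented with that covariate (adjusted p = 0.000465) and against the wider background (1.11e-07). In the test without the covariate their odds ratio was 1.45, and leaving out either of 2 single libraries turned it below 1, to 0.50 with 4 genes without DDX18A 1 and 0.433 with 3 genes without DDX18A 2. A group of 2 needs both, so each gene then needed a peak in DDX18A 3. That library held 6 members, against 16 in DDX18A 1 and 16 in DDX18A 2. The odds ratio also turned with a peak required in all 3 libraries (0.496, 3 genes) and without IgG-overlapping peaks (0.124, 1 gene), and none of the 4 passed (adjusted p = 0.655, 0.655, 0.933 and 0.0508). The 3 calls also ended against the wider background (adjusted p = 0.203, 0.43 and 1), and that of histone genes in DDX18A ended without DDX18A 2 (0.059) and with a peak required in all 3 libraries (0.0885).

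The test of the difference between groups used 836 named genes of DDX18_WT alone and 280 of DDX18A alone. Each had a peak in at least 2 of 3 libraries of that group and in fewer than 2 of the other. Ribosomal protein genes made up 12 of the DDX18A genes and 1 of the DDX18_WT genes (Fisher's exact test, adjusted p = 1.05e-05), with RPL3, RPL30 and RPL35A in 3 of 3 DDX18A libraries and RPL19 in 2. Per library, 2, 0 and 6 members had a peak in DDX18_WT and 16, 16 and 6 in DDX18A (exact permutation p = 0.2, n = 3), so that DDX18A 3 matched DDX18_WT 3. Genes of extracellular matrix and fibrosis made up 6 of the DDX18A genes and 0 of the DDX18_WT genes (Fisher's exact test, adjusted p = 0.0024), while 1 and 7 of 26 members had peaks in the groups (adjusted p of enrichment 0.202 and 0.306). Among these 6 were CCN1, a growth-factor-like matrix protein, and VIM, each with a peak in 0 DDX18_WT and 2 DDX18A libraries. TIMP2 had peaks in 1 and 2, and the integrin gene ITGB1 and the lysyl oxidase gene LOXL2 in 1 and 3. Per library 3, 3 and 2 members had a peak in DDX18_WT and 6, 9 and 5 in DDX18A (exact permutation p = 0.1, n = 3), and all 26 measured members had IgG peaks, as did 98.3% of the 8882 background genes. Over all alternatives the adjusted p ran from 1.81e-07 to 1 for ribosomal proteins and from 0.00105 to 1 for matrix genes. Neither call held at a q of 1e-05 or less or below 0.05 (adjusted p = 1 for each), without IgG-overlapping peaks (adjusted p = 0.487 for ribosomal proteins and 0.207 for matrix genes) or with a peak required in all 3 libraries (0.225 and 0.505). Fewer members were left there, all of them in DDX18A, with 1 ribosomal protein and 2 matrix genes without IgG-overlapping peaks, and 3 and 2 with all 3 libraries required. At a q below 0.05, 4 ribosomal protein genes were left in DDX18A and 0 in DDX18_WT, and matrix genes had 0 in both. The ribosomal protein call also ended with gene length as a covariate (adjusted p = 0.18, with the odds ratio of DDX18_WT over DDX18A moving from 0.0267 to 0.156) and without DDX18A 2 (0.0934, with 3 DDX18A and 2 DDX18_WT genes). Without DDX18A 1 it passed with 4 DDX18A and 2 DDX18_WT genes (adjusted p = 0.0378), and without DDX18A 3 with 11 and 1 (1.81e-07). The matrix call also ended with equal numbers of peaks (0.0875), without DDX18_WT 1 (0.101) and without DDX18_WT 3 (0.148), although the count stayed at 6 against 0 in these 3 settings. Without DDX18A 1, 2 or 3 it was 3, 3 or 4 against 0, and the call held (adjusted p = 0.0378, 0.0219 and 0.0054).

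**Figure D4:**
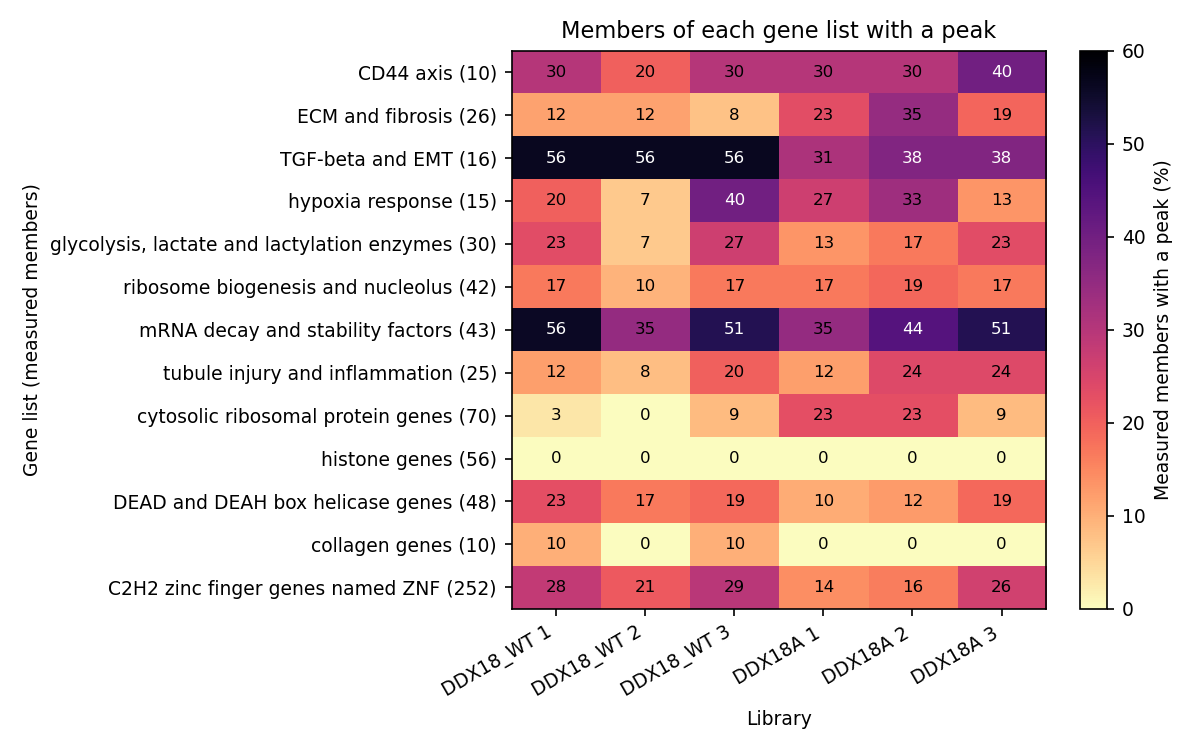
Percentage of the measured members of each gene list with a peak, for the 6 DDX18 libraries on the horizontal axis and the 13 lists with at least 10 measured members on the vertical axis, with the number measured in brackets. Ribosomal protein genes with a peak number 16, 16 and 6 in the DDX18A libraries and 2, 0 and 6 in the DDX18_WT libraries, out of 70.

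Of the other lists named by the authors' gene columns, none passed either test in the main setting. For the CD44 axis, 3 of 10 members had peaks in DDX18_WT and 4 of 10 in DDX18A, MSN in 2 and 0 libraries, SPP1 in 0 and 2 and EZR in 3 and 2. The hypoxia response had 3 and 4 of 15, with HIF1A in 1 and 3 libraries and ARNT in 2 and 0. Glycolysis, lactate and lactylation enzymes had 7 and 5 of 30, with EP300 in 3 and 1, CREBBP in 2 and 0 and LDHA in 0 and 2. Ribosome biogenesis and nucleolus had 5 and 7 of 42, with NOLC1 in 3 and 1, DDX10 in 2 and 0, and FBL and NOP58 in 0 and 2. Tubule injury and inflammation had 3 and 4 of 25, with HAVCR1 in 2 and 3. Proximal tubule differentiation had 1 of 5 in both groups, which was PAX8. DEAD and DEAH box helicases had 9 and 5 of 48, ZNF genes 58 and 42 of 252 and collagen genes 0 of 10 in both groups. Endothelial, leukocyte and fibroblast markers (1 measured each), neuronal genes (6), olfactory receptor genes (3) and mitochondrially encoded genes (9) had 0 in both groups. Some of these lists passed in other settings. The difference between groups in ribosome biogenesis genes passed without DDX18A 3 (3 DDX18_WT and 5 DDX18A genes, adjusted p = 0.0204) and with RefSeq spans (0.0342). ZNF genes were over-represented in DDX18_WT with gene length as a covariate (adjusted p = 0.0112) and with RefSeq spans (0.00684). With gene length, neuronal genes in DDX18_WT and DDX18A (adjusted p = 0.000167 and 0.0221), and collagen (0.023) and matrix genes (0.0453) in DDX18_WT, were under-represented. Matrix genes were over-represented in DDX18A with RefSeq spans, with 9 of 26 (adjusted p = 0.0098). The wider background, which includes genes with no peak in any list, gave 23 calls over lists and groups. Genes of snoRNAs and their hosts, read from RefSeq spans, had 6 and 8 of 146 (Fisher's exact test, adjusted p = 3.22e-05 for under-representation in DDX18_WT and 0.0537 in DDX18A). This call was not run with gene length as a covariate, which ended the calls of histone and ribosomal protein genes. Small nuclear RNA genes, also read from RefSeq spans, had 2 and 6 of 40 (adjusted p = 0.0943 and 0.793). Their difference between groups gave an adjusted p of 0.0342 by Fisher's exact test, although 6, 1 and 7 members per DDX18_WT library and 7, 6 and 0 per DDX18A library had a peak (exact permutation p = 1, n = 3).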

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

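Alternatives with a q below 0.05 or without DDX18A 1 and 2 were chosen after seeing the data, and the cause of the changes below was not tested unless stated. The exonic share and the share overlapping IgG stayed higher in DDX18A, and the Jaccard index within minus between groups stayed above 0, under every alternative run for them (3.16 to 28.0 points, 8.80 to 46.7 points and 13.3 to 20.9 points). Few peaks passed stricter thresholds. At a q of 1e-05 or less, DDX18A had 15.3 more peaks and 4.95 kb more called sequence per library, exclusive regions numbered 0 for DDX18_WT and 2 for DDX18A, exclusive genes 0 and 1, and 0 lists were called in either test. At a q below 0.05 DDX18A had 37 more peaks and 6.10 kb more, with 10 and 10 regions, 7 and 7 genes and 0 and 0 lists, and 0 of the genes at either threshold were among the 197 and 60. Percent of members minus percent of background then turned for TGF-beta genes in DDX18_WT (-0.105 and -0.561), and for mRNA decay factors in DDX18_WT (-0.105 and -0.561) and DDX18A (-0.681 and -0.884), since no member was left. Equal numbers of peaks, which set the difference in peaks to 0, gave 467 regions and 89 genes for DDX18_WT and 1 list in the difference test, where the main setting gave 940, 197 and 2. Without IgG overlap DDX18A had 273 regions and 24 genes, CD44 had 0 libraries and 0 lists differed. With RefSeq spans 10 calls were made over lists and groups (6 in the main setting) and 4 in the difference test, and the share of peaks in no gene turned to 0.376 points higher in DDX18A; exonic classes could not be given there. Gene length as a covariate left 1 list in the difference test, and the wider background gave 23 calls over lists and groups. A peak in at least 2 libraries against none gave 553 and 248 genes, and a peak in all 3 left 0 lists in the difference test. Without DDX18A 1 and 2 there were 3137 regions for DDX18A, and 301 and 457 genes. Leaving out each library in turn, where a group of 2 needs both, gave 1005 to 1915 regions for DDX18_WT and 451 to 1252 for DDX18A, 223 to 430 and 62 to 188 genes, and 1 to 3 lists in the difference test. Deviations of same-numbered libraries correlated at 0.0104, 0.00679 and -0.0119 over regions, and those of other pairs at -0.0369 to 0.0221. These values give no sign that replicate numbers pair the samples. They cannot exclude pairing, since 61.3% of the regions were called in 1 library only. With the numbers as a block the differences were -2144 peaks, -1139.7 kb, 12.6 points of exonic share, 14.4 points of IgG overlap and -0.982 points in no gene, each with an exact sign-flip p of 0.25, the smallest it allows. Of the values for single genes and lists, 536 stayed the same, 84 moved without turning, 6 turned and 25 lost a call. A gene's value stayed the same if unchanged, and a list's if it kept its direction and call. Depth is unknown, so a gene without a peak is not shown to be unbound.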

Other observations

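The strongest peaks named here, the resampling interval and the calculation of what removal alone leaves were chosen after the results were seen, and the other tests before. The strongest peaks differed between the lists, and several lay in noncoding RNAs. By p-value the first peak of all 3 DDX18_WT libraries lay in NEAT1, a nuclear long noncoding RNA (chromosome 11, 65441462 to 65441777 in DDX18_WT 1, fold 3.95), and peaks in an exon of VMP1 and in MALAT1, where TALAM1 overlaps it, were among the first 8 of each. The MALAT1 peaks had low folds, at 1.495, 1.433 and 1.447 in DDX18_WT 1, 2 and 3. All 3 lay within a MALAT1 peak of the IgG list (65499109 to 65501109, fold 7.33), which ranked 10 there by p-value. DDX18A 1 and 2 began with the 3' UTR of ACTB (folds 3.68 and 4.07), followed by NEAT1 at a neighbouring place (65441839 to 65442485 in DDX18A 1), MT2A, YBX1, the ferritin gene FTH1 and RNVU1-31, a variant U1 small nuclear RNA gene. DDX18A 3 began with a peak in an intron of ATXN2 that also overlaps the pseudogene IFITM3P5 (fold 16.6), the 3' UTR of DCBLD2 and VMP1. The IgG list was led by structured noncoding RNAs, with RMRP first (fold 53.8), then RNVU1-28, RNVU1-31, RNU2-2, RN7SK, RPPH1, RN7SL1 and RN7SL2.

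The exonic share was 12.6 points higher in DDX18A. With equal numbers of peaks 100.03% of that difference stayed, which argues against the number of called peaks. Stringency was not made equal, since DDX18A 1 kept all of its 3416 peaks and DDX18_WT 3 its best 3416 of 8174. A role of stringency therefore stays open. Among peaks of 230 to 400 bp 53.0% stayed, between the bounds set for a role of fragment length, so that remains open. In that range the exonic share was 14.7%, 14.4% and 19.2% in DDX18A 1, 2 and 3, on 755, 867 and 2442 peaks. The DDX18_WT libraries had 9.09% to 9.90%. Among peaks without IgG overlap 25.1% stayed, which met the bound set beforehand for transcripts also recovered by IgG, although removing such peaks at equal rates in both groups would alone leave 41.7%. These transcripts may therefore account for part of the difference, while the exonic share of the remaining peaks was still 1.82 times as high in DDX18A and an effect of the DDX18 form, which was not tested, stays open.

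CD44 and the other genes called in DDX18A alone may owe part of their calls to transcripts that IgG also recovers. Genes called in DDX18A alone had a median percentile of 94.6 for their best peak within the IgG list, 23.1 points above genes called in DDX18_WT alone (95% resampling interval over genes, 14.4 to 34.3), and the median over all genes with a DDX18 peak was 84.7. The bound set beforehand was 20 points, which lies inside that interval. Transcript abundance in these cells and the DDX18 form itself were not tested and stay open.

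Weak intronic peaks, with a q of 1, recurred between libraries of a group. They overlapped a peak of another library of the group at least 9.60 times as often as random places in the same genes, which argues against chance placement. Genomic DNA as the source is argued against by 24 long neuronal genes, where peaks per Mb reached at most 0.620% of those over all protein-coding genes. Unspliced RNA bound by DDX18 is a possible explanation that was not tested, and repeats or other sequence that attracts reads stay open too.

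Splits of the 6 libraries number 10, too few for a share under 0.05. In 1 of the 10, the real one, genes called in 3 libraries of a side and 0 of the other numbered 257, and the highest other split gave 112. For regions the real split gave 1358 and the highest other 169, and for the Jaccard index 15.2 points and 3.36. The gene split that gave 112 set DDX18_WT 1, DDX18_WT 3 and DDX18A 3 against the rest, which are the 3 libraries with the most peaks.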
